A study of Saccharomyces cerevisiae with 176 samples.

How the data were processed

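RNA sequencing values of 176 libraries of Saccharomyces cerevisiae in 81 groups were used. They come from 6 batch culture experiments of aneuploid strains, a phosphate-limited chemostat, pooled euploid and aneuploid populations, a WT haploid time course and NaCl-treated W303 cells. The labels give total RNA library preparation for exp1 to exp4 and selection of poly(A) RNA for exp5, exp6 and the populations. Groups, strains, experiments and replicate numbers were taken from the labels. For 2 libraries, exp4 A18 replicate 2 and chemostat A24 replicate 2, the strain field names another strain than the title. They were kept under their titles, since their chromosome profiles resembled the other library of that strain (r of 0.987 and 0.964 across chromosomes). The last time is 26 h in 1 label and 28 h in another, and 26 h was used. The labels give a single growth description for the Tsai and dilution protocols, so how they differ is not given in the sources used here.

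The deposited table holds, per the labels and its own values, log2(TPM + 1) for 6692 genes. Per the submitters' processing notes, the authors aligned reads to sacCer3 with STAR 2.5.3a and estimated expression with RSEM 1.3.0. The annotation of the reference held 7130 identifiers, of which 438 were not in the table, and 4 of these were spike-in controls, with 0 rows in the table. Among its genes, 6008 matched a locus tag of the reference annotation and 5276 had a standard name. Of 5989 nuclear genes with coordinates in both sources 5981 had the same ones. Raw reads were not analysed here, so the depth of each library and the counting error of each value are unknown. On the scale of log2(TPM + 1), fold changes of genes with low TPM are understated. Where summed TPM fell far short of the full total, as in exp1 to exp4, the values are shares of a total that other transcripts dominate.

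Differences were fitted with limma 3.58.1 in R 4.3.3, with a variance prior that follows mean expression, after a filter at a mean log2(TPM + 1) of at least 2 over the libraries of the fit. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. The batch culture fit held 44 libraries of exp1 to exp3 with a term for each strain and experiment, and the mean of 10 aneuploid strains was set against 2N (31 residual degrees of freedom). Libraries of exp4 to exp6 have no 2N control and were compared only strain against strain. The chemostat fit held 20 libraries (10 residual degrees of freedom) and the fit of the difference between settings 64 (41). The population fit held 15 (10) and the time course fit 28 (14). Each batch culture and chemostat strain was also compared with 2N alone. The p-values measure only spread between samples. A difference between ways of growth or library preparation is confounded with any other difference between those sets.

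Of 30 gene lists written before the data were examined, those with at least 3 tested members were tested with limma's camera, with a preset correlation between genes of 0.01 and, as a check, with an estimated one. P-values were adjusted over the lists of each comparison. Beside the calls over all genes, calls adjusted over the list alone are given. A list's relative median is its median log2 change minus the median of all genes tested. Where that median moved by over 0.1, changes of genes are given relative to it too. Their adjusted p-values and calls test the change as measured, before the median is taken off. The mean log2(TPM + 1) of a list's genes in a library is its score. Single genes were named by a rule fixed before the data were examined. It took the 8 largest increases and the 8 largest decreases among called genes with a standard name and 1 direction in every aneuploid strain, or in every library of the first group against the mean of the second. It added up to 4 members of each called list, the called members with the largest changes in the direction of its median, and 10 genes in every comparison: HSP12, CTT1, HSP26, TPS1, RPL3, RPS3, NOP1, NSR1, PHO84 and PHO5. Some genes that the rule names are not reported here.

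Relations across samples were tested with Pearson and Spearman correlations, by exact permutation for 7 or 8 strains and by 100000 random permutations for the time course. Correlations across genes describe similarity only, since genes are not independent replicates. Chromosome medians were computed over the genes of each of 16 nuclear chromosomes as the difference from the 2N mean of the same experiment or setting, relative to all nuclear genes, with a threshold of at least 0.25 in every library of a strain. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

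Replicate numbers were checked for pairing by the correlation of same-numbered libraries after removing group means. These ran from -0.06 to 0.10 in batch culture, from -0.20 to 0.03 in the chemostat, from -0.14 to 0.10 in the Tsai, from -0.11 to 0.06 in the dilution comparison and from -0.29 to 0.25 in the time course. In no comparison did every pair exceed 0.1, so the fits have no term for the replicate. No pair of libraries held identical values. Root mean square log2 differences between replicates had a median of 0.57 in batch culture (70 pairs), 0.5 in the chemostat (10), 0.16 in each of the Tsai groups' pairs (6), 0.17 in the dilution groups (6), 0.14 in WT cells (3) and 0.57 in the time course (14).

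The procedure was tested on simulated data with log2 changes of 0.5, 1 and 2 put into 67, 67 and 66 genes. It recovered 83.6%, 100% and 100% of them in the batch culture design, 23.9%, 70.1% and 93.9% in the chemostat design, 94%, 100% and 100% in a population comparison and 0%, 0% and 25.8% at a single time of the time course. Of the calls 6%, 5.3%, 4.4% and 0% were genes with no change put in. A low count at single times therefore says little about changes under 2. The changed genes had a mean log2(TPM + 1) of at least 4, above the filter at 2, and changed alike in every aneuploid strain. Recovery of lower genes, and the share of false calls where strains differ, were therefore not measured.

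Alternatives tried for the fits were log2(TPM + 5), no filter or a filter at a mean of 4, centring on the median of all genes or of those outside the lists, quantile normalization, a prior without the trend, a term for the replicate, subsets of experiments, strains and library codes, a random block for the strain, and leaving out each library and each strain in turn. Chosen after the values were seen were rescaling TPM to 1 total over the genes of the table without those of the ribosomal DNA locus, centring each chromosome, leaving out strains whose chemostat libraries differ in a chromosome, leaving out the 4 latest times, fits of only exp1 and exp2 or only the 12 population libraries, medians in place of means for list scores, taking the library median off scores, setting each batch culture strain against the 2N of its own experiments only, and other settings for chromosome medians. The NaCl libraries were described but not compared, since no untreated library of their strain was analysed here.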

Results

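RNA abundance was measured by sequencing in 176 libraries of budding yeast (Saccharomyces cerevisiae), which the labels place in 81 groups. The series asked how euploid cells, with whole sets of chromosomes, and aneuploid cells, with single chromosomes gained or lost, differ in expression under different growth conditions. In batch culture in rich medium, 6 experiments (exp1 to exp6) held 14, 14, 16, 18, 24 and 24 libraries, those of a euploid control included. Aneuploid strains are named by the letter A and a number. The euploid control strain 2N was in exp1 (4 libraries), exp2 (2) and exp3 (2), and in none of the other 3. A phosphate-limited chemostat, a culture whose growth rate is set by the dilution rate, gave 2 libraries each of 2N and of 9 aneuploid strains. Both A24 titles share a part of their codes that differs between libraries of the other strains that carry it. Whether they come from separate cultures is therefore not known. Pooled populations of meiotic progeny, euploid from diploids or aneuploid from triploids, were grown by procedures called here the Tsai and the dilution protocol. They gave 3 libraries per population, beside 3 of exponentially growing wild-type (WT) haploid cells. A WT haploid culture was sampled every 2 h at 14 times from 0 h to 26 h, with 2 libraries per time, and 3 libraries came from cells kept in 500 mM NaCl for 40 min. The values carry no read depth, so the counting precision of each value is unknown. Summed over the genes of the table, TPM, a length-scaled share of all transcripts, came to between 5.03% and 7.11% of the full TPM total in exp1 and exp2 and between 7.45% and 12.35% in exp3 and exp4. They came to between 94.95% and 99.63% in exp5 and exp6, between 85.07% and 98.94% in the chemostat and between 15.37% and 97.25% in the time course.

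In batch culture, aneuploid strains were compared with 2N over exp1 to exp3 (10 aneuploid strains, 36 libraries, against 8 libraries of 2N). ALD4 (YOR374W, chromosome XV, 1039840 to 1041399), the mitochondrial aldehyde dehydrogenase, rose by 1.59 ± 0.14 (log2, SE; adjusted p = 7.33e-11), from 2.92 ± 0.29 (SD, n = 8) in 2N to 4.76 ± 0.95 (SD, n = 36). UBI4, the stress-inducible polyubiquitin gene, rose by 1.21 ± 0.14 (adjusted p = 6.76e-08) and IDH2, a subunit of mitochondrial isocitrate dehydrogenase, by 1.13 ± 0.13 (adjusted p = 4.22e-08). AGA1, an agglutinin subunit used in mating, was higher by 1.42 ± 0.18, the iron-retaining cell wall protein gene FIT2 by 1.38 ± 0.26, the ATP synthase subunit gene TIM11 by 1.32 ± 0.35, the cell wall protein gene SPI1 by 1.26 ± 0.38 and TMH11 by 1.14 ± 0.23. LEU2 (YCL018W) changed by -1.24 ± 0.21 (adjusted p = 3.48e-05), HIS4 by -1.04 ± 0.14 (adjusted p = 3.94e-07), URA3 by -1.04 ± 0.25 and the lysine pathway gene LYS21 by -0.79 ± 0.17. The heme pathway gene HEM13, the riboflavin pathway gene RIB4 and RBP95 changed by -0.72 ± 0.14, -0.68 ± 0.13 and -0.68 ± 0.21 (RBP95 at 0.02 in exp3 alone). In the fit of all 3 experiments, with a term for the experiment, the fitted effect of each of these genes had the same sign in 10 of 10 strains. The rule for naming required this. Set against the 2N of their own experiments only, strains differed by the opposite sign in AGA1 (A35, -0.11), FIT2 (A1, -0.09), TIM11 (A27, -0.44), SPI1 (A25, -0.09), URA3 (A18, 0.07), HEM13 (A1, 0.12) and RBP95 (A25, 0.12), 1 strain each. In limma's test, 448 of 3152 genes passed an adjusted p of 0.05, 316 higher and 132 lower (70.5% higher). Centring each library on its median gave 547 genes, 262 higher and 285 lower (47.9% higher). The 448 calls were uneven over chromosomes. On VIII 17 of 142 genes were lower and 3 higher, and on III 10 of 80 and 2, at relative medians of -0.20 and -0.25. On VII 52 of 312 were higher and 3 lower, and on XIV 42 of 245 and 1, at 0.13 and 0.12. LEU2, HIS4 and RBP95 lie on III. The changes given for genes include any shift of their chromosome. Few genes were tested because low TPM values in these libraries fell under the filter, and fold changes of low genes are understated on the log2(TPM + 1) scale. With the strain as a random block, which treats strains and not libraries as the replicates, 1 gene passed; exp1 alone gave 272 genes and exp2 alone 143.

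Of the gene lists fixed in advance, the environmental stress response lists moved in opposite directions in batch culture. Of 50 stress-induced genes tested, 28 rose, none fell and 22 did not pass (34 rose adjusted over the list alone), with a median of 0.57 above the median of all genes. TMA10 rose by 1.43 ± 0.38 in 9 of 10 strains and the trehalose synthesis genes TSL1 and TPS1 by 1.21 ± 0.20 and 0.78 ± 0.13. Of 137 ribosomal protein genes, none rose and 33 fell (42 adjusted over the list alone), with a relative median of -0.24. RPL7B changed by -1.71 ± 0.45, RPS9A by -1.34 ± 0.25, RPS22B by -1.21 ± 0.18 and RPL3 by -0.32 ± 0.06, while RPS3 did not pass (-0.20 ± 0.09, adjusted p = 0.134). Reads of such duplicated genes may be split between copies. Of 144 ribosome biogenesis genes, 9 fell (2 adjusted over the list alone) and none rose, with a relative median of -0.18. At a filter at a mean of 4 this median was -0.06, and the list was not called (adjusted p = 0.332). UTP9 changed by -0.58 ± 0.15 and NOP1, the nucleolar methyltransferase fibrillarin, by -0.29 ± 0.08, while NSR1 was at 0.16 ± 0.07 and did not pass. In camera's test with a preset correlation the adjusted p was 1.48e-14 for the stress-induced list, 1.48e-14 for ribosomal proteins and 2.18e-05 for ribosome biogenesis. The calls were lost with an adjusted p = 0.0591, adjusted p = 0.0697 and adjusted p = 0.401, respectively, with an estimated correlation.

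Other lists moved as well. Of 19 cell wall integrity genes 12 rose and none fell (15 rose adjusted over the list alone; adjusted p = 4.03e-12, and adjusted p = 0.0113 with an estimated correlation), among them the glucan synthase gene GSC2 (0.97 ± 0.11), SRL3 (0.88, but -0.43 in exp2 alone), HSP150 (0.80 ± 0.09) and CWP1 (0.76). Of 47 respiration and TCA cycle genes 16 rose and none fell (25 rose adjusted over the list alone; adjusted p = 2.81e-09, and adjusted p = 0.0271 with an estimated correlation), such as LSC2 (1.05 ± 0.14) and the citrate synthase gene CIT1 (0.84 ± 0.14). Of 47 amino acid biosynthesis genes 20 fell and 2 rose (24 and 3 adjusted over the list alone; adjusted p = 1.61e-12, and adjusted p = 0.0201 with an estimated correlation), with BAT1, a branched-chain aminotransferase, at -0.84 ± 0.09. Among 22 heat shock chaperones 6 rose (7 adjusted over the list alone), including HSP104 (0.78 ± 0.14) and SSA1 (0.58 ± 0.11), and among 33 proteasome genes 9 rose, including PRE9 (0.50 ± 0.11); adjusted over the list alone, 14 proteasome genes rose and 1 fell. Of 12 phosphate starvation genes 5 fell, such as the phosphate transporter gene PHO84 (-1.06 ± 0.15) and VTC3 (-0.81 ± 0.12), and 1 rose (the same counts adjusted over the list alone). Of 13 G2 and M phase genes 3 rose (5 rose and 1 fell adjusted over the list alone), with the chitinase gene CTS1 at 0.95 ± 0.06. These 4 lists had a camera adjusted p = 0.0148, adjusted p = 0.0016, adjusted p = 0.011 and adjusted p = 0.0148; with an estimated correlation each call was lost, at adjusted p = 0.36, adjusted p = 0.292, adjusted p = 0.301 and adjusted p = 0.36. Genes of mating cells were higher in the mean: 3 of 4 genes of alpha cells rose (4 of 4 adjusted over the list alone; adjusted p = 1e-05, and adjusted p = 0.0119 with an estimated correlation) and 5 of 5 haploid-specific genes (5 adjusted over the list alone; adjusted p = 5.73e-07, and adjusted p = 0.0232 with an estimated correlation). The alpha pheromone gene MF(ALPHA)1 was at 2.01 ± 0.18 but higher in only 6 of 10 strains.

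Fitted strain by strain, the stress response lists pointed 1 way in most batch culture strains. The number of genes that differed from 2N ran from 63 in A1 and 67 in A25 to 926 in A23 and 997 in A21, with a median of 342.5. This median was 207 at a filter at a mean of 4 and 153.5 after centring each chromosome. These counts follow the number of libraries, with 63 to 269 genes in strains with 2, 416 and 455 with 4 and 759 to 997 with 6, so they do not rank the strains. After centring on the median of all genes A1 had 16 and A25 109. The median of the ribosomal protein list lay below the median of all genes in 10 of 10 strains, from -0.43 in A21 to -0.10 in A35, and that of the ribosome biogenesis list in 9 of 10, from -0.40 in A23 to 0.02 in A35. The stress-induced list lay above it in 8 of 10 strains, from -0.08 in A35 to 1.23 in A21. In the chemostat the same lists spread to both sides: ribosomal proteins were above in 5 of 9 strains and below in 4 (-0.72 in A18 to 0.87 in A23), ribosome biogenesis above in 6 (-0.38 in A18 to 0.31 in A22) and the stress-induced list above in 7 (-0.70 in A34 to 0.92 in A21). The stress-induced score minus the library median was 1.96 in chemostat 2N. It was 2.52, 3.10 and 2.89 in A20, A21 and A23, which share the library code of 2N. In the strains of another code it ran from 1.34 in A34 to 2.65 in A38. For this list the spread to both sides cannot be told apart from the library code. All strains of a setting share its 2N libraries. In 100 simulated sets of unchanged strains against those libraries, as many strains lay on 1 side in 4 sets for batch culture ribosomal proteins, in 20 for ribosome biogenesis and in 35 for the stress-induced list. The median of the strain medians was 0.59 for the batch culture stress-induced list, against 0.28 at most in the simulated sets, and -0.27 for ribosomal proteins, against a largest size of 0.18. In the chemostat the values were 0.42 for the stress-induced list, against 0.54, and 0.16 for ribosomal proteins, against 0.97.

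**Figure D1:**
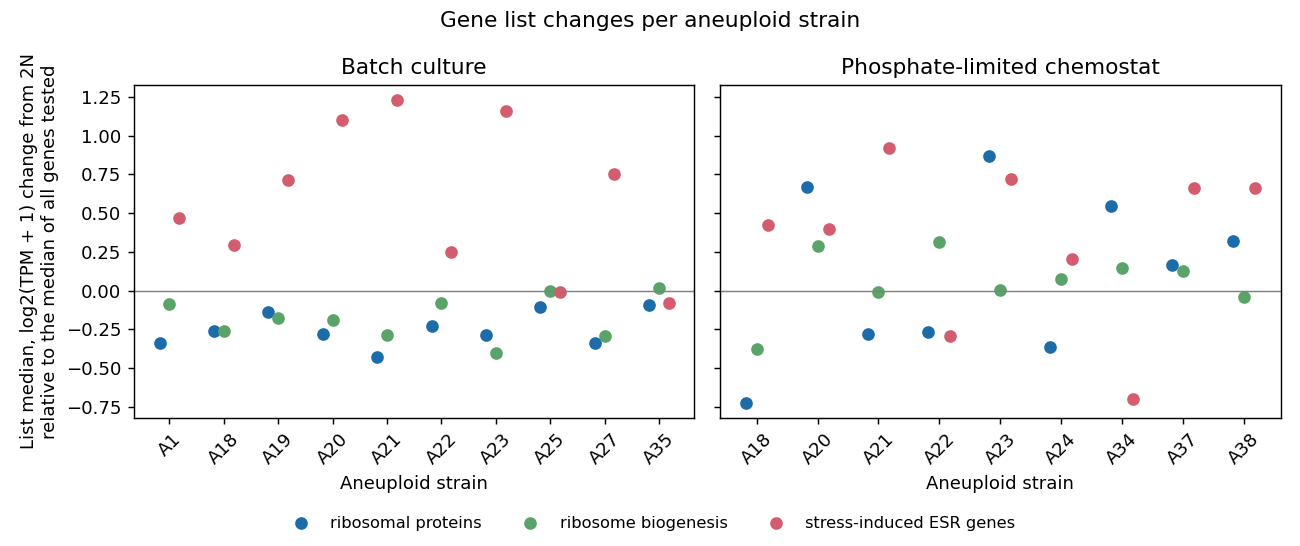
Median log2(TPM + 1) change from 2N of 3 gene lists (y axis, relative to the median of all genes tested) for each aneuploid strain (x axis) in batch culture (10 strains) and in the chemostat (9 strains); each point is 1 list in 1 strain. The ribosomal protein points of batch culture lie below 0 in 10 of 10 strains, while in the chemostat they run from -0.72 to 0.87.

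In the chemostat, strains and 2N grew at 1 fixed dilution rate, and 9 aneuploid strains (18 libraries) were compared with 2N (2 libraries). The median of all genes shifted by -0.17, and the changes given are relative to it. Adjusted p-values of genes and counts of calls, here and below, are of changes as measured unless centring or another setting is named. FKS1 (YLR342W), the main glucan synthase subunit, rose by 2.13 ± 0.28 (SE, adjusted p = 0.000707), the peptide transporter gene PTR2 by 2.15 ± 0.41 and the RNA-binding protein gene SRO9 by 2.41 ± 0.53. RPL41A (2.65 ± 0.57), SFK1 (1.99 ± 0.44) and the near-identical enolase-related genes ERR1 and ERR2 (2.13 ± 0.49) rose as well. PMP2, a proteolipid of the plasma membrane proton pump, changed by -3.32 ± 0.56 (adjusted p = 0.00162), the uracil permease gene FUR4 by -2.89 ± 0.51, the aquaporin gene AQY2 by -2.39 ± 0.62 and the cytochrome c oxidase subunit gene COX7 by -2.13 ± 0.35. SET6, ZPS1, NRS1 and DPA10 changed by -2.19 ± 0.42, -2.18 ± 0.35, -2.15 ± 0.40 and -2.03 ± 0.51. These genes changed the same way in 9 of 9 strains, which the rule for naming required, and all strains share the 2 libraries of 2N. Of 5674 genes 907 passed in limma's test, 164 higher and 743 lower (18.1% higher). Centring gave 616, 290 higher and 326 lower (47.1% higher). The 2N libraries set the count: without 2N replicate 1 it was 147 and without replicate 2 193, where the remaining library is assumed to vary like the other groups. Libraries of 2N, A20, A21 and A23 carry another library code (d204, shared with exp6) than the other chemostat libraries, and with only these 531 genes passed.

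Of 21 phosphate starvation genes in the chemostat, 12 fell and none rose (17 fell adjusted over the list alone, and 5 after centring). The acid phosphatase genes PHO11, PHO12 and PHO5 changed by -1.83 ± 0.25, -1.36 ± 0.24 and -0.66 ± 0.21, and PHO84 by -0.48 ± 0.17 in 9 of 9 strains. Camera gave an adjusted p = 2.19e-06, and an adjusted p = 0.139 with an estimated correlation. Of 22 cell wall integrity genes 6 rose and none fell (6 adjusted over the list alone; adjusted p = 9.67e-08, and adjusted p = 0.0172 with an estimated correlation), such as CWP1 (1.49 ± 0.32), YPS1 (1.24 ± 0.22) and SED1 (1.16 ± 0.18). All 5 genes of alpha cells rose (5 adjusted over the list alone), with MF(ALPHA)1 at 3.38 ± 0.31 but higher in only 4 of 9 strains, and 9 of 16 haploid-specific genes rose (10 adjusted over the list alone), such as FAR1 (3.18 ± 0.25). These calls held at adjusted p = 0.000624 and adjusted p = 0.0118 with an estimated correlation. Of 80 stress-induced genes 9 rose and 7 fell (10 and 8 adjusted over the list alone), with a relative median of 0.40; the transketolase gene TKL2 was at 2.69 ± 0.69 and the catalase gene CTT1 at 1.62 ± 0.39 (7 of 9 strains). Camera's adjusted p = 0.000101 became an adjusted p = 0.82 with an estimated correlation. Among 138 ribosomal protein genes 1 rose and 1 fell (none adjusted over the list alone). The median was -0.07, or 0.10 relative to all genes, and camera's call of a higher list (adjusted p = 0.0493) became an adjusted p = 0.898 with an estimated correlation. The relative median was -0.03 without 2N replicate 2 and 0.23 without replicate 1, and the call was lost without any 1 of 9 of the 20 libraries. Ribosome biogenesis genes (2 of 148 fell, none adjusted over the list alone; adjusted p = 0.233) did not pass. RPL3 (0.48, adjusted p = 0.584), HSP12 (0.83, adjusted p = 0.33) and TPS1 (0.59, adjusted p = 0.392) did not pass either.

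Among the other chemostat lists, 16 of 47 respiration and TCA cycle genes fell and 1 rose (19 and 3 adjusted over the list alone; 8 and 3 after centring; adjusted p = 0.0335, and adjusted p = 0.865 with an estimated correlation), with QCR10 at -0.87 ± 0.15. Of 24 ergosterol genes 6 fell (9 adjusted over the list alone; adjusted p = 0.00103, and adjusted p = 0.3 with an estimated correlation), including ERG28 (-1.23 ± 0.16) and ERG5 (-0.88 ± 0.14). Heat shock chaperones (1 of 29 rose, 1 adjusted over the list alone, SSA2 at 0.92 ± 0.14 in 6 of 9 strains but at -0.33 with only the d204 libraries) had a relative median of 0.46 and S phase genes (1 of 25 rose, none adjusted over the list alone) of 0.87. Their adjusted p = 2.57e-05 and adjusted p = 9.75e-06 became an adjusted p = 0.492 and an adjusted p = 0.82 with an estimated correlation. Of 17 DNA damage response genes 2 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.0493, and adjusted p = 0.524 with an estimated correlation), with RNR3 at 1.04. No difference from the median of all genes passed for proteasome, glycolysis, amino acid, iron or oxidative stress lists. For glycolysis this mean averages unlike strains. A20, A21 and A23, which share the code d204 with 2N, were at -0.42, -0.47 and -0.97. The other 6 strains ran from -0.21 to 0.44.

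The difference between the settings was tested itself over the 5 strains grown in both, A18, A20, A21, A22 and A23, with 64 libraries in 1 fit. The median of all genes shifted by 0.13, and values are relative to it. The filter took the mean over all 64 libraries, so 5064 genes were tested, against 3152 in the batch culture fit. Genes added in this way are low in batch culture, where the log2(TPM + 1) scale understates changes. A difference between the settings can arise from that alone. ALD4 changed more in batch culture by 2.39 ± 0.29 (adjusted p = 5.59e-08), the hexokinase gene HXK1 by 1.89 ± 0.47 and CIT1 by 1.35 ± 0.29, and the daughter-cell wall genes CTS1, DSE2 and SCW11 by 1.56 ± 0.13, 1.53 ± 0.19 and 1.35 ± 0.23. TKL2 and NQM1, of the pentose phosphate pathway, differed the other way by -3.23 ± 0.59 and -3.11 ± 0.69, and the chaperone gene SSA2 by -0.91 ± 0.13. Of 47 respiration genes 9 were higher in batch culture relative to the chemostat and none lower (34 adjusted over the list alone, 2 after centring), with a relative median of 0.84 (adjusted p = 7.17e-23, and adjusted p = 0.000732 with an estimated correlation). No ribosomal protein gene and no ribosome biogenesis gene differed in limma's test, alone or over all genes, and their relative medians were -0.30 and -0.23. Of 80 stress-induced genes 10 were higher and 4 lower (18 and 4 adjusted over the list alone), with a relative median of 0.22. Camera called these 3 lists (adjusted p = 4.49e-06, adjusted p = 0.000483 and adjusted p = 0.0214), each lost at an adjusted p = 0.634 with an estimated correlation. In all, 135 of 5064 genes passed, 110 higher and 25 lower (81.5% higher; after centring 103, with 56.3% higher). Without chemostat 2N replicate 1 the count was 52 and without replicate 2 38, and library type and setting cannot be told apart. Between the 2 contrasts, fold changes had a Pearson correlation of 0.141 across 3092 genes, which are not independent replicates. Both contrasts called 39 genes higher (10.8 if independent) and 11 lower (11.7 if independent).

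In the Tsai protocol, aneuploid populations were compared with euploid ones (3 libraries each). The hexose transporter gene HXT2 (YMR011W, chromosome XIII, 288079 to 289704) rose by 2.83 ± 0.05 (SE, adjusted p = 7.69e-17), from 4.44 ± 0.05 (SD, n = 3) to 7.27 ± 0.08 (SD, n = 3), and HXT1 and HXT3 rose by 2.62 ± 0.07 and 2.56 ± 0.05, although reads of such paralogs may be split. NSR1, the nucleolin homolog, rose by 2.41 ± 0.04 (adjusted p = 7.69e-17), the RNA helicase genes DHR2 and DBP2 by 2.63 ± 0.11 and 2.5 ± 0.05, the IMP dehydrogenase gene IMD2 by 2.41 ± 0.07, and BSC1 and JJJ3 by 3.13 ± 0.12 and 2.42 ± 0.17. The small heat shock protein gene HSP26 changed by -2.20 ± 0.04 (adjusted p = 1.27e-16), from 11.29 ± 0.06 to 9.09 ± 0.03 (SD, n = 3 each), and HSP12 by -2.18 ± 0.07. The mitochondrial pyruvate carrier gene MPC3 changed by -3.17 ± 0.07, the maltase gene MAL12 by -2.91 ± 0.19, and the stationary phase and desiccation genes SPG1, GRE1, SIP18 and SPG4 by -2.70 ± 0.15, -2.62 ± 0.14, -2.58 ± 0.18 and -2.33 ± 0.18. TDH1 and LEU2 were at -2.40 ± 0.07 and -2.56 ± 0.06. All had the same sign in 3 of 3 libraries, which the rule for naming required of the largest changes. Of 5699 genes 4313 passed in limma's test, 2338 higher and 1975 lower. The low spread between these libraries lets small changes pass.

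By list in the Tsai protocol, 134 of 138 ribosomal protein genes rose and 3 fell, with a relative median of 0.50, and RPL3 and RPS3 were at 0.48 ± 0.03 and 0.23 ± 0.04 (RPS3 at -0.01 after quantile normalization). Of 148 ribosome biogenesis genes 146 rose and none fell, with a relative median of 1.43, and of 24 RNA polymerase I and III genes all 24 rose, such as RPA49 (2.02). Of 80 stress-induced genes 72 fell and 5 rose, with a relative median of -0.88; CTT1 changed by -0.25 ± 0.08 and TPS1 by -0.28 ± 0.04. Camera gave an adjusted p = 1.86e-22, adjusted p = 1.75e-34, adjusted p = 3.49e-10 and adjusted p = 3.87e-19. With an estimated correlation the lists were at adjusted p = 0.197, adjusted p = 0.158, adjusted p = 0.158 and adjusted p = 0.158, and no list of this comparison kept its call. Respiration genes fell (43 of 47, 1 rose; LSC2 at -1.25 ± 0.05), as did mitochondrial ribosomal proteins (59 of 67, 2 rose), gluconeogenesis and derepressed carbon genes (20 of 25, 2 rose; PCK1 at -2.03) and osmotic stress genes (15 of 20, 4 rose). Amino acid genes rose (39 of 52, 5 fell; HOM3 at 2.07 and ASN1 at 1.92), as did translation factors (37 of 39, 2 fell), heat shock chaperones (22 of 29, 3 fell; SSA2 at 2.06 ± 0.06), iron genes (16 of 22, 1 fell) and S phase genes (21 of 25, 1 fell; RNR1 at 1.86). Haploid-specific genes fell (15 of 17, none rose), as did all 5 genes of alpha cells (STE3 at -1.20). Adjusted over the list alone, these counts were the same except that 1 ribosome biogenesis gene, 60 mitochondrial ribosomal protein genes and 16 haploid-specific genes fell. The estimated-correlation values of these 11 lists ran from adjusted p = 0.158 to adjusted p = 0.37.

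In the dilution protocol the ribosomal and stress lists moved the other way between aneuploid and euploid populations (3 libraries each). The median of all genes shifted by 0.27, and values are relative to it. HSP12 (YFL014W) rose by 2.57 ± 0.07 (SE, adjusted p = 3.3e-15), from 6.63 ± 0.03 to 9.47 ± 0.06 as measured (SD, n = 3 each), CTT1 by 1.62 ± 0.08 and HSP26 by 0.78 ± 0.04. The carbonic anhydrase gene NCE103 rose by 3.12 ± 0.08 (adjusted p = 2.93e-15), the proline oxidase gene PUT1 by 2.97 ± 0.11, the amino acid catabolic gene ARO10 by 2.65 ± 0.08 and the serine pathway gene SER3 by 1.80 ± 0.05. The cell wall genes HPF1 and NCW2 and the G1 cyclin gene PCL1 were at 2.21 ± 0.06, 1.94 and 1.91 ± 0.11. LEU2 changed by -2.92 ± 0.06 (adjusted p = 1.28e-15), and the phosphate genes PHO11, PHO5, PHO12, PHM6 and PHO89 by -2.43 ± 0.10, -2.41 ± 0.06, -2.05, -2.04 ± 0.17 and -2.02 ± 0.09. The mating genes FIG1 and PRM3 were at -2.11 ± 0.04 and -2.01 ± 0.10. RPL3, RPS3 and NSR1 changed by -0.70 ± 0.03, -0.82 ± 0.04 and -1.01 ± 0.04. All had the same sign in 3 of 3 libraries, which the rule for naming required of the largest changes. Of 5699 genes 4328 passed in limma's test, 3470 higher and 858 lower (80.2% higher). Centring gave 3717, 1901 higher and 1816 lower (51.1% higher).

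By list in the dilution protocol, 124 of 138 ribosomal protein genes fell and 5 rose (126 and 5 adjusted over the list alone; 132 and 1 after centring), with a relative median of -0.58 (adjusted p = 1.78e-53, and adjusted p = 0.0449 with an estimated correlation). With quantile normalization this median was only -0.11, with 76 lower and 22 higher. Of 148 ribosome biogenesis genes 110 fell and 10 rose (112 and 10 adjusted over the list alone), at -0.57 (adjusted p = 5.66e-35, and adjusted p = 0.0648 with an estimated correlation). Of 80 stress-induced genes 66 rose and 5 fell (the same adjusted over the list alone; 51 and 13 after centring), at 0.22 (adjusted p = 2.03e-05, and adjusted p = 0.406 with an estimated correlation). Phosphate starvation genes fell (18 of 21, 1 rose), as did genes of alpha cells (5 of 5), of a cells (6 of 7) and haploid-specific genes (15 of 17, 1 rose), and all 10 histone genes rose, such as HTB2 (1.72 ± 0.04). These 5 lists kept their calls with an estimated correlation, at adjusted p = 0.0188, adjusted p = 0.0345, adjusted p = 0.0449, adjusted p = 0.0345 and adjusted p = 0.0449. Glycolysis genes fell (14 of 17, 1 rose), and cell wall (21 of 22; PIR1 at 1.5 ± 0.05), S phase (24 of 25, 1 fell) and G2 and M phase genes rose (24 of 25, 1 fell; CDC5 at 1.19 ± 0.05). Their adjusted p = 1.58e-10, adjusted p = 3.75e-06, adjusted p = 0.000439 and adjusted p = 3.75e-06 became adjusted p = 0.146, adjusted p = 0.183, adjusted p = 0.268 and adjusted p = 0.268 with an estimated correlation. The counts of these 9 lists were the same adjusted over the list alone. All 33 proteasome genes, 37 of 47 respiration genes and 59 of 67 mitochondrial ribosomal protein genes were called higher as measured, against 16, 19 and 27 after centring, when 3, 10 and 9 were called lower. Their relative medians were 0.07, 0.05 and 0.09.

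The dependence of the aneuploid effect on the protocol was tested as an interaction over the population libraries. Values relative to the shift of -0.26 were -4.76 ± 0.10 for HSP12 (adjusted p = 1.6e-16), -2.99 ± 0.06 for HSP26, 3.41 ± 0.06 for NSR1 (adjusted p = 1.49e-16) and 1.17 ± 0.05 for RPL3. Of 138 ribosomal protein genes 135 were higher in the Tsai protocol's effect and 1 lower (136 and 1 adjusted over the list alone; relative median 1.11, and 0.60 with quantile normalization), of 148 ribosome biogenesis genes 147 were higher (147 adjusted over the list alone; 2.04), and of 80 stress-induced genes 75 were lower and 2 higher (the same adjusted over the list alone; -1.05). Camera's adjusted p = 4.86e-46, adjusted p = 3.22e-54 and adjusted p = 2.32e-15 became adjusted p = 0.109, adjusted p = 0.075 and adjusted p = 0.162 with an estimated correlation. In all, 4277 of 5699 genes passed, 1407 higher and 2870 lower (32.9% higher, and 45.2% of 4159 after centring).

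The euploid populations of the protocols were also compared with each other, relative to a shift of 0.18. HSP26 was higher in the Tsai euploid population by 6.62 ± 0.04 (adjusted p = 3.92e-24), HSP12 by 5.61 ± 0.07, GRE1 by 5.20 ± 0.14 and SIP18 by 5.03 ± 0.18. NSR1 was lower by a change of -3.31 ± 0.04, RPL3 of -1.16 ± 0.03 and PHO89 of -4.81 ± 0.09. Of 80 stress-induced genes 77 were higher, and 136 of 138 ribosomal protein and 145 of 148 ribosome biogenesis genes were lower, at relative medians of 1.13, -0.84 and -1.65 (counts the same adjusted over the list alone). Camera's adjusted p = 5.04e-17, adjusted p = 1.7e-35 and adjusted p = 2.64e-43 became adjusted p = 0.146, adjusted p = 0.146 and adjusted p = 0.144 with an estimated correlation. Of 5699 genes 4533 passed, 2867 higher and 1666 lower (63.2% higher, and 53.2% of 4586 after centring).

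**Figure D2:**
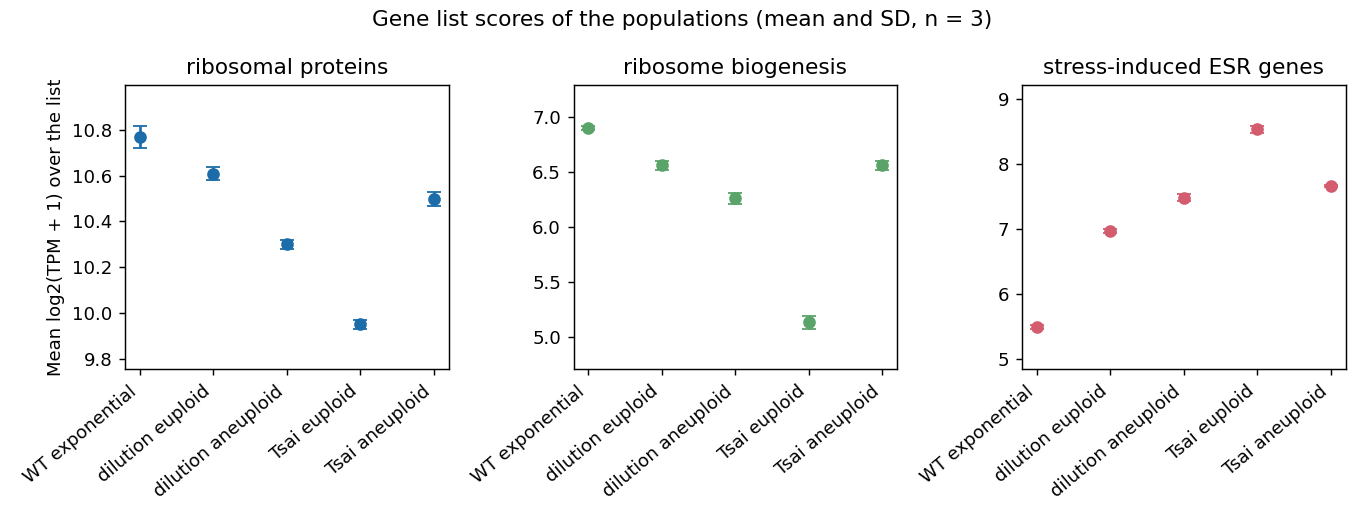
Mean log2(TPM + 1) over the genes of 3 lists (y axes, 1 panel per list) in the WT exponential, dilution and Tsai populations (x axis); points are means and bars SD over 3 libraries. The stress-induced score runs from 5.49 in WT cells to 8.53 in the Tsai euploid population, where the ribosomal protein (9.95) and ribosome biogenesis (5.13) scores are lowest.

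Set beside exponentially growing WT cells (3 libraries), the Tsai euploid population had HSP12 higher by 9.15 ± 0.07 (SE, adjusted p = 1.45e-23), HSP26 by 8.19 ± 0.04, SPG1 by 6.14 ± 0.15 and the high-affinity glucose transporter gene HXT6 by 4.79 ± 0.08, and NSR1 and RPL3 at -3.35 ± 0.04 and -1.07 ± 0.03. All 80 stress-induced genes were higher, and 137 of 138 ribosomal protein and 148 of 148 ribosome biogenesis genes were lower (adjusted p = 2.38e-25, adjusted p = 1.43e-25 and adjusted p = 2.1e-31; adjusted p = 0.135, adjusted p = 0.193 and adjusted p = 0.135 with an estimated correlation). In the dilution euploid population the glycogen phosphorylase gene GPH1 was higher by 4.05 ± 0.07, HSP12 by 3.36 ± 0.07 and HSP26 by 1.38 ± 0.04, and NSR1 and RPL3 were at -0.23 ± 0.04 and -0.09 ± 0.03 (RPL3 at 0.02 after quantile normalization). Of 80 stress-induced genes 77 were higher and 1 lower (adjusted p = 2.32e-33, and adjusted p = 0.0468 with an estimated correlation). Of 138 ribosomal protein genes 97 were lower and 2 higher, and of 148 ribosome biogenesis genes 98 and 8 (adjusted p = 4.69e-05 and adjusted p = 7.83e-06; adjusted p = 0.601 and adjusted p = 0.546 with an estimated correlation). All 10 histone genes were lower, with HTB2 at -2.42 ± 0.04, while the cell surface protein gene STE3 of alpha cells was at 8.05 ± 0.06, since the WT haploid is an a strain by its high STE2. Adjusted over the list alone, these counts were the same. In limma's test 4815 and 4065 of 5699 genes passed.

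In the time course of the WT haploid, at 14 h against 0 h (2 libraries each), HXK1 was higher by 6.26 ± 0.54 (SE, adjusted p = 5.27e-13), GPH1 by 5.88 ± 0.55, HSP26 by 5.82 ± 0.55, HXT4 by 4.64 ± 0.53 and HSP12 by 4.60 ± 0.55, and DHR2 was at -2.30 ± 0.51 and PHO11 at -3.26 ± 0.57. Of 78 stress-induced genes 41 rose at 14 h (64 adjusted over the list alone) and 27 of 148 ribosome biogenesis genes fell (97 adjusted over the list alone), while no ribosomal protein gene was called. At 16 h, relative to a shift of 0.24, HSP12 was at 11.40 ± 0.55, HSP26 at 10.01 ± 0.55, HXT6 at 9.15 ± 0.60, RPL14A at -5.85 ± 0.53 and the helicase gene HAS1 at -5.87 ± 0.58. There 77 of 78 stress-induced genes rose (78 adjusted over the list alone), and 136 of 138 ribosomal protein and 144 of 148 ribosome biogenesis genes fell (136 and 146 adjusted over the list alone), with relative medians of 3.83, -4.33 and -3.83. Camera's adjusted p at 16 h was 1.45e-43, 6.43e-59 and 9.52e-53 for the 3 lists, and adjusted p = 0.373, adjusted p = 0.36 and adjusted p = 0.36 with an estimated correlation. Limma called 2 genes at 2 h, 0 at 4 h (23 at an unadjusted p under 0.05), 2 at 6 h, 5 at 8 h, 4 at 10 h, 31 at 12 h, 208 at 14 h and 2286 at 16 h. After centring these 8 counts were 34, 32, 113, 197, 211, 552, 1742 and 3671. Leaving out 1 library of 0 h or 14 h brought the count at 14 h to between 75 and 98, the lower without 0 h replicate 2.

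By 26 h, relative to a shift of -1.10, the vacuolar protein gene EGO4 was higher by 11.06 ± 0.55 (SE, adjusted p = 5.78e-21), HSP12 by 10.11 ± 0.55, SPG4 by 9.51 ± 0.57, HSP26 by 9.42 ± 0.55, HSP30 by 8.80 ± 0.55, the gluconeogenic gene FBP1 by 8.76 ± 0.57, SPG1 by 8.71 ± 0.63 and HXT6 by 8.38 ± 0.60. RPL37A was at -6.13 ± 0.57, PHO12 at -6.06 ± 0.59, UTR2 at -5.92 ± 0.50, the low-affinity glucose transporter gene HXT3 at -5.83 ± 0.53, SNU13 at -5.78 ± 0.53 and ANB1, DBP2 and RPL22B at -5.69 ± 0.49, -5.69 ± 0.60 and -5.68 ± 0.58. All 138 ribosomal protein genes, 145 of 148 ribosome biogenesis genes, 23 of 24 RNA polymerase I and III genes and 44 of 51 amino acid genes fell, as did 15 of 17 glycolysis genes (1 rose), such as the pyruvate decarboxylase gene PDC1 (-4.65 ± 0.55). Of 78 stress-induced genes 56 rose, of 47 respiration genes 41 (SDH1 at 5.78 ± 0.55), of 28 gluconeogenesis and derepressed carbon genes 22 (2 fell; PCK1 at 8.20 ± 0.55) and of 19 stationary phase genes 12. Adjusted over the list alone, 45 amino acid genes fell and 1 stress-induced gene fell, and the other counts were the same. All these list counts are of changes as measured, which include the shift of -1.10. Camera called each of these 9 lists, the largest adjusted p = 0.00263 being that of glycolysis; with an estimated correlation none held, from adjusted p = 0.289 to adjusted p = 0.773. Of 5444 genes 3021 passed, 471 higher and 2550 lower (15.6% higher); centring gave 3745, 1859 higher and 1886 lower (49.6% higher). Summed TPM fell far short of the full total in the latest libraries, so that values at those times are shares of a different total.

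**Figure D3:**
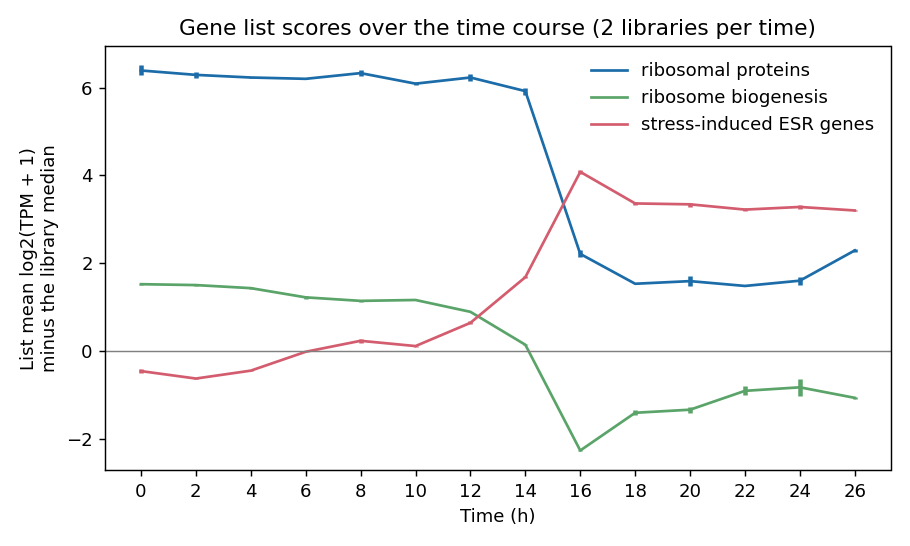
Mean log2(TPM + 1) over 3 gene lists minus the library median (y axis) against time in h (x axis) in the WT haploid culture; lines join means of 2 libraries and vertical bars span both. The ribosomal protein score goes from 5.92 at 14 h to 2.21 at 16 h, while the stress-induced score goes from 1.68 to 4.08.

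Over the 28 time course libraries, the ribosomal protein score had a Pearson r of -0.885 and a Spearman coefficient of -0.897 with time, the ribosome biogenesis score -0.912 and -0.902 and the stress-induced score 0.764 and 0.815. Each had a permutation p of 1e-05, the smallest that 100000 permutations can give, except 2e-05 for the Pearson r of the stress-induced score. Adjusted over these 6 values they were 1.2e-05 and 2e-05. Libraries of the same or neighbouring times of a culture may not be independent, which these p-values do not take into account. Without 2 of the 4 libraries farthest from the median time, in 6 ways, r lay between -0.89 and -0.879, between -0.914 and -0.901 and between 0.738 and 0.788. In the ribosomal protein and ribosome biogenesis scores, libraries up to 14 h and from 16 h lie apart, so r describes a step there more than an even slope. The stress-induced scores overlap, with 14 h libraries at 6.46 and 6.81 and the lower of 24 h at 5.89, and lie apart only with the library median taken off.

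Fold changes of the populations were set against those of the time course across 5416 genes, which are not independent replicates. The change of the Tsai euploid population from WT cells had its largest Pearson correlation with the change at 16 h (0.83, and 0.81 outside the 3 stress response lists), as did that of the dilution euploid population (0.52, and 0.51 outside them). The Tsai aneuploid against euploid change correlated at -0.77 with the change at 16 h (-0.76 outside the lists) and the dilution change at 0.40 (0.30 outside them). Each of these changes shares its euploid libraries, with opposite sign, with the change of that population from WT cells. The values are therefore not separate evidence, and for the Tsai protocol a negative value follows in part from the 0.83. The mean change of the batch culture strains correlated at 0.427 with it across 3070 genes (0.346 outside the lists).

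Experiments without 2N can be compared only strain against strain. Over the 7 strains shared by exp3 and exp4, deviations of the stress-induced score from the experiment mean had a Pearson r of 0.875 (exact permutation p = 0.0183) and a Spearman coefficient of 0.786 (exact permutation p = 0.048); without A22 and A25 r was 0.853. Adjusted over the 12 values of the 6 relations they were 0.219 and 0.274, so this did not pass. The ribosomal protein score had an r of 0.703 and a Spearman coefficient of 0.607 (exact permutation p = 0.0685 and 0.167; 0.542 without A18 and A21), and the ribosome biogenesis score an r of 0.15 and a Spearman coefficient of -0.0714 (exact permutation p = 0.752 and 0.906; -0.695 without A18 and A21). Over the 8 strains of exp5 and exp6, r and the Spearman coefficient were 0.534 and 0.429 for the stress-induced score (exact permutation p = 0.174 and 0.299; 0.505 without A32 and A34), 0.495 and 0.429 for ribosome biogenesis (exact permutation p = 0.213 and 0.299; 0.177 without A26 and A38) and 0.22 and 0.19 for ribosomal proteins (exact permutation p = 0.59 and 0.665; -0.00886 without A30 and A32). The adjusted values ran from 0.219 to 0.906.

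At the main setting 33 strain and chromosome pairs stood apart over the 10 batch culture strains of exp1 to exp3, but only 5 did with log2(TPM + 5), so most of these calls depend on the scale. Strains of exp4 to exp6 were not assessed, for lack of 2N. Taking a strain's chromosome as higher or lower where the median over its genes differed from 2N by at least 0.25 (log2, relative to all nuclear genes) in every library, chromosomes VII, IX, X and XI were higher in A18 (0.35, 0.37, 0.36 and 0.31 over 2 libraries), VII and XIII in A20 (0.29 and 0.35 over 6) and XIII in A1, and chromosome XVI was lower in A21 (-0.31 over 6). A35 had 6 higher chromosomes, I, V, VII, IX, XI and XII, and A27 had II, X, XI, XIII and XIV higher and VIII lower. A25 had II, VII and XIV higher, A19 had V and XVI lower, A22 III, V, IX, XII and XIII, and A23 III, VII and XVI. In the chemostat A18 had VII, IX, X, XI and XVI higher, A20 VII, IX, XIII, XIV and XV higher and I lower. A21 had II and IV higher and 9 chromosomes lower, A22 had none, with libraries that differed by over 0.25 in 8 chromosomes, and A23 had IX, XI and XIV higher and III lower. The chemostat strains A24, A34, A37 and A38 had 4, 4, 5 and 4 chromosomes higher and none lower. Across the 16 chromosomes, the chemostat profiles of A18, A20, A21 and A23 correlated with their batch culture profiles at 0.95 to 0.99, and the chemostat libraries of A22 at 0.51 and 0.85. The labels give no karyotypes, so these values were not set against chromosome counts. Being relative to all nuclear genes, a chromosome called lower need not have been lost where others are higher. In chemostat A21, VII, XIII, XIV and XV had medians of 0.28, 0.26, 0.25 and 0.25 but were not called. Since every library must pass, the rule is stricter for strains with more libraries, and the numbers of calls do not rank the strains.

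In the 3 libraries of W303 cells kept in 500 mM NaCl, the glycerol synthesis gene GPD1 was at 6.57 ± 0.08 (log2, SD, n = 3), the sodium pump gene ENA1 at 4.55 ± 0.16, HSP12 at 8.98 ± 0.11, CTT1 at 5.39 ± 0.15 and RPL3 at 6.80 ± 0.19. List scores were 5.48 ± 0.04 for ribosomal proteins, 2.13 ± 0.04 for ribosome biogenesis and 3.92 ± 0.06 for stress-induced genes. No untreated W303 library was analysed here and the strain background differs from that of the other cells, so no comparison was made. One row of the ribosomal DNA locus, YLR154W-C, took between 47.5% and 59.96% of the summed TPM. That sum came to 14.01% to 20.52% of the full total. The same gene took 4.28% to 41.78% in exp3, 0% to 8.73% in exp2 and 0% in exp1, which are in 1 fit.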

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

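Tests chosen only after the result was seen were the centring of chromosomes and the difference between settings for the stress-induced list, the comparison of the aneuploid populations and quantile normalization for the protocols, and the chromosome III median for LEU2. These results were set apart for a closer look because a difference between 2 effects was itself tested, or because 1 library lay apart from its group. The protocol changed the aneuploid effect for 4277 genes, with relative list medians of 1.11 for ribosomal proteins, 2.04 for ribosome biogenesis and -1.05 for stress-induced genes. The difference between aneuploid strains and 2N itself differed between batch culture and chemostat for 135 genes, and for 75 after rescaling. It rests on 2 chemostat libraries of 2N, and library type and setting cannot be told apart. Among the 4 libraries of 2N in exp1, replicate 3 had a ribosomal protein score whose gap to the nearest other was 0.843 of the range, above the 95% critical value of Dixon; chance gives such a gap in about 1 in 20 groups.

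The first pattern is the higher stress-induced list of the batch culture strains. Centring every chromosome left its relative median at 0.62. Chromosome medians of this mean ran only from -0.25 (III) to 0.13 (VII), so centring could not have removed the list's change. Shifts of the genes' own chromosomes are thus too small to be the whole cause. Effects of a gained or lost chromosome on genes of other chromosomes were not tested. The lowest of 3 experiments fitted alone gave 0.52, which argues against a difference between experiments. Growth rate stays open. The list's difference between batch culture and chemostat was 0.22, called by camera (adjusted p = 0.0214). With an estimated correlation it was at an adjusted p = 0.634, so a part that depends on growth rate cannot be told apart from none. Stress-induced genes of 2N scored 2.43, 1.95 and 1.81 in exp1 to exp3, against 7.76 in the chemostat. Changes of such low genes are understated on the log2(TPM + 1) scale, which can lower this difference. A direct effect of aneuploidy on stress genes also stays open as untested.

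The second pattern is the opposite direction of the stress response lists in the populations. The stress-induced list differed by 0.07 between the Tsai and dilution aneuploid populations (quartiles -0.27 and 0.61), against 1.13 between the euploid ones (quartiles 0.65 and 1.77). Single genes of the list thus differed between the aneuploid populations in both directions. A candidate explanation is the state of the euploid controls. These differences use the same groups as the interaction, so they are not separate evidence for it. The difference between the euploid populations also followed the change at 16 h of the time course across genes outside the lists. The Pearson correlation was 0.68 (genes not independent replicates), as a difference in growth phase would give. From 12 h to 26 h it lay between 0.53 and 0.68. Any other difference in state that moves the same genes would give it too, so growth phase is not singled out. Quantile normalization left the stress-induced list at 0.33 in the dilution and -0.87 in the Tsai protocol. This argues against the authors' TPM scaling for that list. TPM scaling applies 1 factor per library, and a relative median takes such a shift off. For ribosomal proteins the -0.58 of the dilution protocol (-0.61 to -0.55 with 1 library left out) therefore argues against it. Quantile normalization left -0.11 and 0.42 for ribosomal proteins, both called by camera. It forces 1 distribution on all libraries, so the drop from -0.58 does not bear on that scaling. Aneuploidy itself as the reason that the aneuploid populations differ less stays open.

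The third pattern is the lower LEU2, a marker that the labels also place on a plasmid of the populations, by relative changes of -2.61 and -2.92. Genes of chromosome III had relative medians of at most 0.12, which argues against fewer copies of that chromosome. The 7 other genes tested of the leucine and valine pathway all rose in the Tsai protocol (median 1.45), which argues against a common regulation of the pathway there. In the dilution protocol they went both ways, from -0.77 (LEU9) to 0.74 (LEU1) with a median of 0.29, so none fell as far as LEU2, but a part of its fall from regulation is not excluded. A lower share of cells with the LEU2 plasmid, or fewer copies of it, may remain and was not tested.

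Other splits of the same libraries were drawn before the result was seen. Of 100 splits, only the real 1 gave as many genes for batch culture (448, highest other 1). The same held for the median over its strains (342.5, highest other 0). The other splits put libraries of unlike strains under 1 strain label, which raises the spread and leaves few genes to call. They show that libraries of a strain resemble each other, and cannot exclude chance for the contrast with 2N. Libraries of a strain are also repeats, and with the strain as a random block 1 gene passed in batch culture. For the interaction also only the real 1 of 100 splits gave 4277 genes, but the highest other gave 4226, which points to a structure of the samples: splits that exchange all labels of 1 protocol keep the groups whole. With 3 libraries against 3 the splits are too few for a share under 0.05: the real split gave 4313 genes for the Tsai comparison (highest other 0), 4328 for dilution (0), 4533 for the euploids (0), 4815 for Tsai euploid against WT (1) and 4065 for dilution euploid against WT (0).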

How the results depend on the processing

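Alternatives chosen only after the values were seen were rescaling to the genes of the table, chromosome centring, leaving out the strains whose libraries differ in a chromosome or the 4 latest times, fits of only exp1 and exp2 or only the 12 population libraries, list medians, taking the library median off, setting each batch culture strain against the 2N of its own experiments only, and the settings for chromosome medians; the others were chosen before the data were examined. The cause was not tested for any change given here.

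For the batch culture mean (448 genes), a filter at a mean of 4 gave 263 genes, exp1 alone 272, exp2 alone 143 and the strain as a random block 1. Leaving out 1 library gave between 379 and 500 and 1 strain between 333 and 514. The median over single strains (342.5) was 207 at a filter at a mean of 4 and 153.5 after chromosome centring. At a filter at a mean of 4 there were 7 called lists in place of 12, and the ribosome biogenesis median was -0.06 in place of -0.18. That median was -0.12 with log2(TPM + 5), -0.11 with no filter and -0.12 with chromosome centring. The stress-induced median (0.57) was 0.90 in exp2 alone, and that of ribosomal proteins (-0.24) was -0.39 in exp3 alone.

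For the chemostat mean (907), rescaling gave 484 genes, chromosome centring 563, only the libraries that share the code d204 with 2N 531 and the 5 shared strains 244. Leaving out 1 library gave between 147 and 1059, with 147 without 2N replicate 1 and 193 without 2N replicate 2. Of its lists 17 in place of 11 were called with only the d204 libraries. The ribosomal protein median (0.10, barely called) lost its call with log2(TPM + 5) at 0.08, no filter 0.07, median centring 0.10, centring outside the lists 0.10, quantile normalization 0.01, rescaling 0.08, chromosome centring 0.14, without the A24 library whose labels disagree 0.10, with the 5 shared strains 0.05 and without the strains whose libraries differ in a chromosome 0.06. It lay between -0.03 (without 2N replicate 2) and 0.23 (without 2N replicate 1) when 1 library was left out and between 0.02 and 0.20 when 1 strain was. It lost its call without 2N replicate 2 (-0.03), A18 replicate 1 (0.03), A20 replicate 1 (0.04), A21 replicate 2 (0.07), A22 replicate 1 (0.09), A24 replicate 2 (0.10), A34 replicate 2 (0.04), A37 replicate 2 (0.03) or A38 replicate 2 (0.05), and without strain A20 (0.05), A23 (0.02), A34 (0.04) or A37 (0.10). The ribosome biogenesis median became called at 0.13 without the strains whose libraries differ in a chromosome, and lay between -0.03 and 0.15 with 1 library left out (called only without A18 replicate 2, at 0.15). For the difference between settings (135), log2(TPM + 5) gave 468, rescaling 75 and only A20, A21 and A23 292. Leaving out 1 library gave between 38 (without chemostat 2N replicate 2) and 175, with 52 without chemostat 2N replicate 1.

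In the time course, the count at 14 h (208) was 360 with log2(TPM + 5), 1742 with median centring, 1724 with centring outside the lists, 1882 with quantile normalization, 1451 with rescaling, 1718 with chromosome centring, 1291 without the 4 latest times and between 75 and 98 with 1 library left out: 88 and 75 without 0 h replicate 1 and 2, and 81 and 98 without 14 h replicate 1 and 2. The count at 16 h (2286) was 3671 with median centring, 3675 with centring outside the lists, 3747 with quantile normalization, 3651 with chromosome centring and 3601 without the 4 latest times. The count at 26 h (3021) was 1930 at a filter at a mean of 4. The correlation of the stress-induced score with time was 0.907 with the library median taken off. The list median in place of the mean gave an r of 0.619 for ribosome biogenesis over exp5 and exp6, and log2(TPM + 5) left 5 chromosome calls in batch culture in place of 33. A term for the replicate as a block gave 458 genes in batch culture, 813 in the chemostat and 4311 in the Tsai comparison.

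The Tsai, dilution, interaction, euploid and WT comparisons of the populations had no total of called genes that moved by over 1.5 times under any setting tried. The split by direction did move in the dilution comparison, from 3470 higher and 858 lower to 1901 and 1816 with median centring. Quantile normalization gave medians of -0.11 in place of -0.58 for ribosomal proteins and 0.33 in place of 0.22 for stress-induced genes in the dilution comparison, and 0.60 in place of 1.11 for ribosomal proteins in the interaction. Of 993 results for named genes over 24440 settings, 23149 were the same, 1227 weaker, 46 stronger and 18 reversed. Reversed in the batch culture mean were TDH3 (-0.31 with quantile normalization), GPM1 (0) and PDI1 (-0.02) in exp1 alone, SRL3 (-0.43) in exp2 alone and RBP95 (0.02) in exp3 alone. In the dilution comparison these were TRP1 (-0.03 with median centring, -0.04 with centring outside the lists, -0.01 with quantile normalization), HIS3 (0 with centring outside the lists) and SBA1 (-0.01 with chromosome centring). With quantile normalization RPS3 (-0.01) reversed in the Tsai comparison and RPL3 (0.02) in dilution euploid against WT. In the chemostat with only the d204 libraries these were SSA2 (-0.33), RPN9 (0.06), MRPL25 (0.08), RAD54 (-0.01), MFA1 (0.17) and STE2 (0.43).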

Other observations

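The tests of this part, of mating-type genes, marker genes, similar strains and unlike replicates, were all chosen only after the values were seen. Mating-type genes parted the aneuploid strains. STE3, the receptor gene of alpha cells, was high in A21 (5.30 ± 0.11 in exp1, log2, SD), A18 (5.09 ± 0.06 in exp3) and A22 (5.75 ± 0.26 in exp3), with n = 2 each, and, with n = 3 each, in A26 (8.15 ± 0.21 in exp6), A30 (8.70 ± 0.05) and A38 (8.44 ± 0.05). STE2, the receptor gene of a cells, was high in A23 (5.19 ± 0.19 in exp1), A27 (4.88 ± 0.28 in exp3; n = 2 each) and A28 (7.89 ± 0.11 in exp6, n = 3). In 2N of exp1 they were at 0.98 ± 0.99 and 0.71 ± 0.81 (SD, n = 4). The higher means of alpha-cell and haploid-specific genes in the report are therefore averages over strains of unlike mating type.

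Marker genes parted the populations from the WT haploid. HIS3 was at 5.62 in the dilution and 5.66 in the Tsai euploid population and at 0.00 in WT cells, and TRP1 at 5.91, 6.44 and 0.05. URA3 was at 0.05 and 0.00 in these populations and at 5.77 in WT cells. The HO endonuclease gene was read in all of them (3.84, 3.67 and 5.33). The WT cells thus differ from the populations in genotype, so the contrasts with WT carry more than the way of growth.

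A32 and A34 had nearly the same chromosome profile, with r between 0.997 and 0.998 in exp5 and between 0.994 and 0.997 in exp6. Their libraries differed by 0.229 to 0.289 (root mean square log2) in exp5, where libraries of the same strain differed by 0.196 to 0.293 and those of other strains had a median of 0.622. In exp6 the differences were 0.298 to 0.406, against 0.217 to 0.241 within A32, 0.211 to 0.266 within A34, 0.203 to 0.595 within all strains and a median of 0.728 between strains, so there the 2 strains did part. Whether they share a karyotype, or whether a label is wrong, is not decided by these values.

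Chemostat libraries of the same strain differed by over 0.25 in 12 strain and chromosome pairs over 5 strains, and by up to 0.62, while the largest differences in exp1, exp2 and exp3 were 0.2, 0.17 and 0.17. Of these pairs 8 were of A22 (chromosomes I, III, IV, V, IX, XI, XII and XIII). For chromosome V of A18 the libraries were at -0.06 and 0.36 and for chromosome I of A34 at -0.02 and 0.60. Cultures that gained or lost chromosomes may be mixed into these means, which was weighed only by leaving out those strains, when the relative median of ribosomal proteins was 0.06 and that of ribosome biogenesis 0.13.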
